A study of Mus musculus with 2 samples.

How the data were processed

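Colon tumours of AOM/DSS-treated mice were profiled by single-cell RNA sequencing (10x Genomics 3′ chemistry, v3). By its label, 1 library came from mice whose intestinal epithelium keeps Gsk3b (IEC+/+, called the WT library here). The other came, by its label, from mice whose epithelium has lost it (IEC−/−, the KO library). The number of animals behind each library is not given in the sources used here. The deposited matrices hold whole-number UMI counts for 32285 genes and for every barcode, with or without a cell; per the file headers they were written by Cell Ranger 4, and the submitters name the mouse build mm10 and also Seurat, without its role. The annotation release is not given in the sources used here. The WT matrix held 164574326 UMIs in 2446729 barcodes and the KO matrix 156641780 UMIs in 2457921 barcodes.

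Cells were called per library with a test against free RNA. The profile of free RNA came from barcodes with under 100 UMIs, barcodes with 500 or more UMIs were tested with 10000 Monte Carlo draws, and those at a Benjamini-Hochberg FDR of 0.001 or less were kept, along with all barcodes above 9138 (WT) and 8352 (KO) UMIs. This called 12283 and 13114 barcodes. Barcodes with under 200 genes or over 25% mitochondrial UMIs were removed (1453 and 1487 for the mitochondrial limit), then the highest Scrublet scores at a rate of 0.8% per 1000 cells (938 and 1081 barcodes), which left 9889 WT and 10546 KO cells. Scrublet's own threshold removed 1 WT barcode and 380 KO barcodes and was not used. The median cell had 5214 UMIs in the WT and 3410.5 UMIs in the KO library.

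Counts per 10000 were log transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 gave 32 clusters over both libraries, without batch integration, because library and genotype coincide. Clusters were named from fixed markers of 17 classes: at least 3 markers had to be present in 25% of cells and stand 2-fold above the 25th percentile of cluster means. That last reference was changed after the data were examined, since a fold over all other cells was diluted for the epithelium, the largest class. Epithelial and T cells were clustered again at resolution 0.6 and named from 10 sub-type lists. A cluster with enough markers still went unnamed where another class or sub-type had more markers among its 10 leading genes. So did some clusters of few UMIs per cell with no marker of their best-scoring class among those genes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9 were used.

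Shares of cells carry exact (Clopper-Pearson) 95% intervals. For expression, UMIs were summed over the cells of a class in each library and divided by the class total (CPM), with exact Poisson intervals, and the log2 ratio of KO over WT CPM carries an exact conditional binomial interval. All these intervals cover counting error only: with 1 library per genotype no test was run and no p-value computed, and no difference has a replicate check. Classes with 100 or more cells in both libraries were compared: epithelial cells, T cells, B cells, monocytes or macrophages, and neutrophils. The 48 gene lists were fixed before the data were examined, as were the markers and the rules below; a list's value is the median log2 ratio of members with 20 or more UMIs, with its percentile among 10000 random lists matched on expression, as a description. In simulated sums at the same depth, the interval of a gene set to 1.5-fold excluded 0 for 85.3% of genes in the epithelial class and 50.0% in B cells; for a 2-fold gene these were 98.4% and 81.0%, and for unchanged epithelial genes 4.91%.

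Named genes followed a rule. Gsk3b, Gsk3a, Ctnnb1, Axin2 and Apc are always named, Gsk3b in every class; of genes with 50 or more UMIs, a CPM of 30 or more in the higher library and there not below that library's empty droplets, the 12 highest and 12 lowest in the epithelial class and 4 and 4 in each other class were taken by the bound of the interval nearest 0. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, T cell receptor variable, predicted and sex-linked genes were left out of that ranking. Of a gene list, up to 4 members beyond 1.5-fold with the most UMIs are named. A gene at 0 UMIs was set to 3 counts to give a bound. Coordinates come from GENCODE vM21 (GRCm38, mm10), matched by Ensembl identifier for all 66 named genes.

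The alternatives were: every barcode with 1000 or 500 UMIs, a 10% mitochondrial limit, no doublet removal, Leiden resolutions of 0.5 and 2, each library clustered alone, subclustering at 0.3 and 1, median-of-ratios scaling, class totals without mitochondrial and ribosomal genes, a mean over cells, subtraction of free RNA (contamination of 10.1% in the WT and 17.6% in the KO library, from immunoglobulin UMIs outside B and plasma cells), cells thinned to the same depth, and list members with 50 UMIs. After the data were examined, settings without 3 shallow epithelial clusters, without epithelial subclusters with over 90% of their cells in 1 library, in stem- or progenitor-like cells only, with subclusters of 100 or more cells in both libraries weighted alike, without B cells holding a Siglech UMI, and with free RNA subtracted at the share from haemoglobin UMIs (41.2% in the WT and 17.9% in the KO library) were added, as were the epithelial settings in the other classes. Dendritic, mast, plasma and endothelial cells and fibroblasts were too few in 1 or both libraries for a comparison of expression and are given as shares.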

Results

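Colon tumours labelled as having lost epithelial Gsk3b were compared with tumours labelled as keeping it, 1 library for each genotype. The KO tumour sample held more neutrophils, B cells and fibroblasts and fewer macrophages, dendritic cells and mast cells as shares of all cells. Its epithelium as a whole had more goblet-like cells and higher goblet RNA, which was not higher over all goblet-like cells. Its T cells were less often named regulatory or type 17 or gamma-delta, and more often CD8 cytotoxic or naive, at the subclustering used. They also carried less Il17a RNA. Gsk3b transcripts themselves differed little between the libraries.

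Gsk3b had 26432 UMIs in WT and 22775 in KO epithelial cells (265 and 241 CPM), a log2 ratio of −0.13 (interval −0.16 to −0.11). It was −0.14 in T cells (−0.31 to 0.034), 0.075 in B cells (−0.41 to 0.59), 0.050 in monocytes or macrophages (−0.060 to 0.16) and 0.25 in neutrophils (0.097 to 0.39). Fibroblasts had 220 and 204 CPM, endothelial cells 251 and 241 CPM, and the empty droplets 167 and 147 CPM. Within stem- or progenitor-like epithelial cells alone the ratio was 0.0096. The gene lies on chromosome 16 from 38089001 to 38246084 (mm10); the deleted part is not given in the sources used here, and UMIs count the 3′ end of transcripts, so a tag outside that part checks neither the deletion nor the assignment of the libraries. In the epithelial class Gsk3a was at −0.086 and Apc at 0.0085, while Ctnnb1 (503 and 404 CPM, −0.32) and Axin2 (103 and 82.7 CPM, −0.32) were lower in the KO library. The Y-linked Ddx3y, Uty, Eif2s3y and Kdm5d were read in both libraries (Ddx3y at 69.6 and 57.4 CPM), with Xist at 0.641 and 0.233 CPM in epithelial cells.

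Neutrophils and B cells made up more of the KO sample, and mononuclear phagocytes less. Epithelial cells were 44.5% (43.5 to 45.5) of WT and 40.7% (39.7 to 41.6) of KO cells. The direction turned with every barcode of 500 UMIs (37.9% and 38.9%), at Leiden resolution 0.5 and when each library was clustered alone (log2 0.024). In the last setting 415 WT cells of a cluster that scored highest for epithelial markers went unnamed. With such unnamed clusters counted the log2 ratios were −0.062, −0.13 and −0.12 in these settings. Epithelial cells were the largest class in both libraries with the main settings. In the KO library neutrophils were the largest with a 10% mitochondrial limit (39.7% against 34.5% epithelial cells). Neutrophils were 27.6% of WT and 35.1% of KO cells, monocytes or macrophages 13.0% and 7.28%, and T cells 8.14% and 7.20%. B cells were 1.20% and 4.78%, 3.97-fold apart, and fibroblasts 0.273% (27 cells) and 1.98% (209 cells), 7.26-fold apart. Fibroblasts were 0.424% and 1.82% with every barcode of 500 UMIs and 0.480% and 2.31% without doublet removal. Dendritic cells were 2.06% and 0.863%, mast cells 1.51% and 0.597%, plasma cells 0.445% and 0.673%, and endothelial cells 0.415% and 0.664%. With every barcode of 500 UMIs plasma cells were 42 WT and 44 KO cells, and endothelial cells 0.694% and 0.605%. A cluster of 86 WT and 22 KO cells led by the defensin genes Defa24, Defa21 and Defa22 was given no name. With immune cells alone as the denominator, neutrophils were 51.2% and 62.1%, monocytes or macrophages 24.1% and 12.9%, and B cells 2.23% and 8.46%. With neutrophils also taken out, T cells were 30.9% and 33.6%, and B cells 4.57% and 22.3%.

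**Figure D1:**
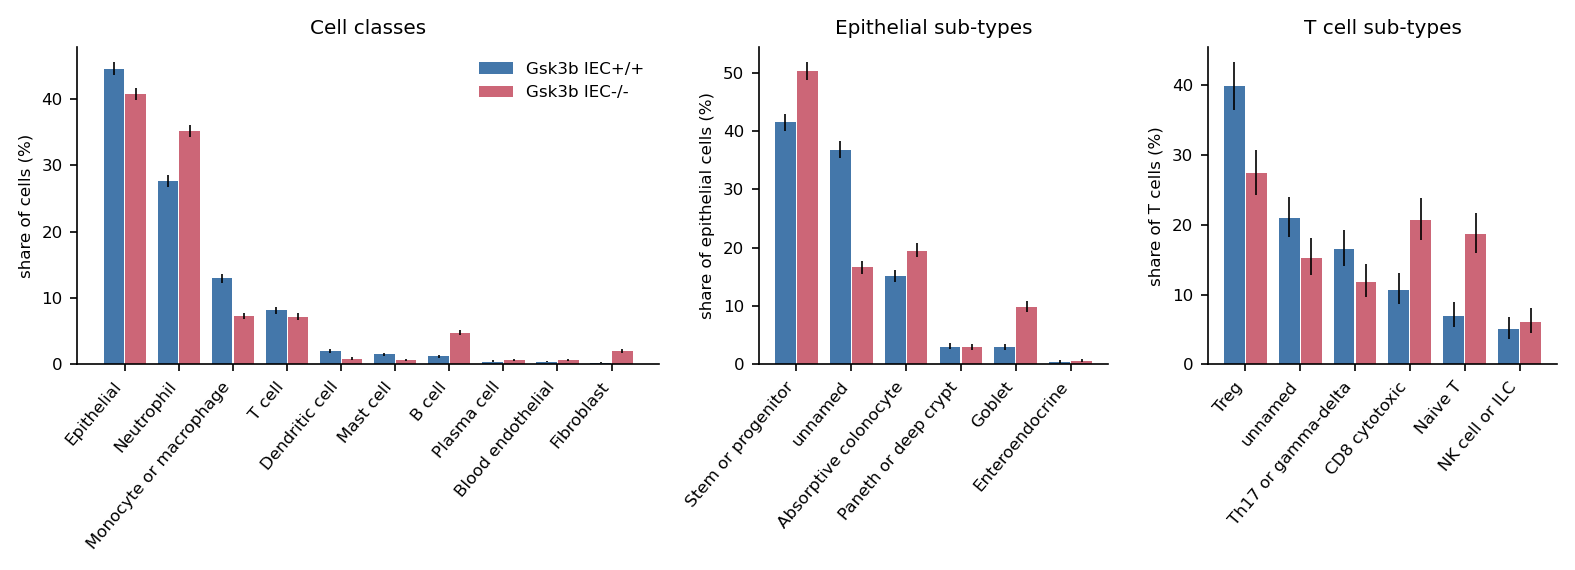
Shares (%) of all cells per class (left), of epithelial cells per sub-type (middle) and of T cells per sub-type (right) in the IEC+/+ (blue) and IEC−/− (red) libraries; error bars are exact 95% binomial intervals, counting error only. Goblet-like cells were 2.93% and 9.88% of epithelial cells, and Treg-like cells 39.8% and 27.4% of T cells.

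Within the epithelium, goblet-like and absorptive cells held larger shares of the KO library. Stem- or progenitor-like cells were 41.5% of WT and 50.3% of KO epithelial cells, but 59.0% and 60.8% at subclustering resolution 0.3. With unnamed clusters counted that scored highest for their markers, the shares at 0.3 were 78.9% and 71.0%, so the direction turned. Absorptive colonocytes were 15.2% and 19.5%, and goblet-like cells 2.93% and 9.88% (3.37-fold). The absorptive subcluster led by Muc3, Sycn and Adh1 held 122 WT and 352 KO cells. The other absorptive subclusters held 194 and 207, 152 and 154, and 200 and 125. At resolution 0.3 goblet-like cells were 1.14% and 5.57%. They were 5.82% and 10.3% with an unnamed cluster counted that scored highest for goblet markers. That cluster was led by Lyz1, Ang4 and Clps, with 3 goblet and 5 Paneth-like markers among its leading genes, so the second pair may count Paneth-like cells. Paneth-like or deep crypt secretory cells were 3.07% and 2.91%, enteroendocrine cells 0.454% and 0.676%, and cells in subclusters without a name 36.8% and 16.7%. Of the goblet-like cells, 1 subcluster led by Zg16, Klk1, Sval1 and Retnlb held 46 WT and 210 KO cells. Another, led by the mitotic genes Birc5, Cdca3 and Ccna2 with no goblet marker among its leading genes, held 12 WT and 136 KO cells. The last, led by Fcgbp, Tff3 and Clca1 with a median of 16.6% mitochondrial UMIs, held 71 WT and 78 KO cells. At resolution 1 goblet-like cells were 2.75% and 7.41%, and a cluster led by Cdca3, Birc5 and Ccna2 (59 WT and 146 KO cells) was named absorptive. An unnamed subcluster led by Cadps, Gkn3, Tgm4 and Rarb held 469 WT and 10 KO cells.

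In epithelial expression, genes such as Fcgbp, Klk1 and Agr2 were higher in the KO library, and genes such as Cadps, Gkn3 and Hdac9 were lower. The 12 genes furthest above WT were Mptx1 (5.63 and 119 CPM, log2 4.40), B3gnt7 (13.6 and 62.9 CPM, 2.21), Fcgbp (47.3 and 189 CPM, interval 1.95 to 2.04), Klk1 (1.95), Muc3 (64.4 and 228 CPM, 1.83), Rep15 (1.88), Clstn2 (57.7 and 165 CPM, 1.51), Hsd11b2 (1.54), Agr2 (556 and 1439 CPM, 1.37), Abcb1a (1.37), Adh1 (1.20) and Itih5 (1.21). Mptx1 is uncertain, because its close paralog Mptx2 stood the other way (27.9 and 0.148 CPM, −7.56) and reads of near-identical genes can be counted for either. Within stem- or progenitor-like cells alone Clstn2 stayed at 1.52, whereas Agr2 was at 0.36, Hsd11b2 at 0.45, Rep15 at 0.68 and Adh1 at −0.17. The 12 genes furthest below WT were Cadps (118 and 21.8 CPM, −2.44), Gkn3 (47.4 and 9.47 CPM, −2.32), Hdac9 (31.8 and 6.27 CPM, −2.35), Gstm7 (−2.02), Sox17 (111 and 28.2 CPM, −1.98), Aspa (−1.94), Kcnb2 (133 and 36.9 CPM, −1.85), Rarb (−1.86), Stra6 (−1.83), Dab1 (−1.69), Fbxo32 (−1.67) and Plat (322 and 117 CPM, −1.46). Cadps, Gkn3 and Rarb lead the subcluster with 469 WT and 10 KO cells; without the subclusters held by 1 library Gkn3 was at −1.41, Rarb at −1.21 and Cadps at −1.81. Hdac9 stood at −1.87, Kcnb2 at −1.44, Sox17 at −1.30 and Fbxo32 at −1.47 in stem- or progenitor-like cells.

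**Figure D2:**
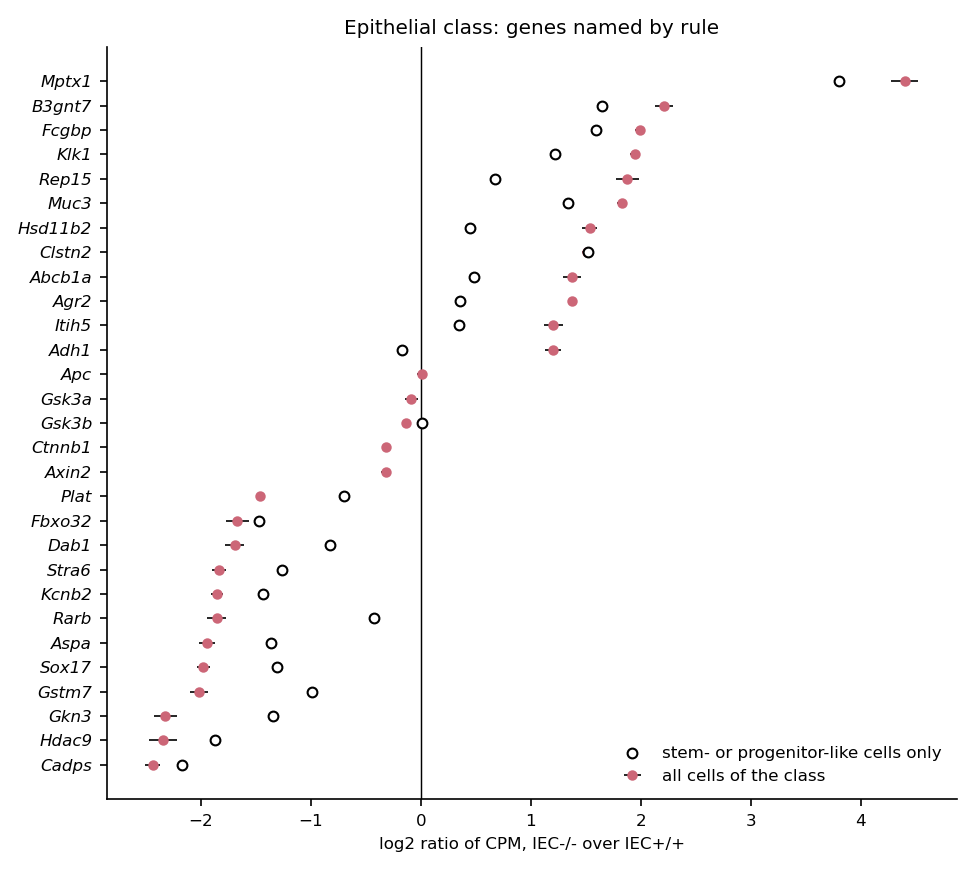
Log2 ratio of CPM (horizontal axis), IEC−/− over IEC+/+ library, of the genes named by rule in the epithelial class; red points with bars are all epithelial cells with exact 95% counting intervals, and open circles are stem- or progenitor-like cells alone. Gsk3b stands at −0.13 and 0.0096, Clstn2 at 1.51 and 1.52, and Adh1 at 1.20 and −0.17.

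Among the gene lists in the epithelium, goblet genes stood high and Wnt targets, type I interferon and tuft genes stood low. All 12 goblet genes were higher in the KO library (median log2 1.34, percentile 100 of the matched random lists; Tff3 1.38, Zg16 3.24, Spink4 1.19), and the median was 0.57 in stem- or progenitor-like cells. Within goblet-like cells it was −0.47, with 0 genes higher and 5 lower beyond 1.5-fold (Muc2 −0.76). By subcluster it was 0.15 in the one led by Zg16 and Klk1, −0.13 in the one led by Fcgbp and −0.98 in the mitotic one, with 12 WT cells. The same list was also higher in T cells (1.47), B cells (1.94), monocytes or macrophages (1.08) and neutrophils (1.31 to 1.62); Agr2 stood at 58.0 and 150 CPM in T cells, beside 521 and 1298 CPM in the empty droplets. Absorptive genes had a median of 0.55 (Guca2a 0.89 and Aqp4 0.66 higher, Slc9a3 −1.37 and Saa1 −0.78 lower), which turned to −0.17 in stem- or progenitor-like cells.

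Wnt targets had a median of −0.26 (percentile 0), with 24 of 30 members below 0, of which Lef1 (−0.60), Apcdd1 (−0.90), Mmp7 (−0.74) and Dkk2 (−0.58) were among the 6 beyond 1.5-fold; Lgr5 was higher (152 and 201 CPM, 0.40). Within stem- or progenitor-like cells together the Wnt median was 0.010 and Axin2 stood at 0.021. Their subclusters differed: the median was −0.31 in the one led by Fut9 and Fstl4 (Axin2 −0.34). It was 0.043, −0.038 and 0.055 in those led by Unc5d, Clstn2 and Ube2c. Wnt list members such as Lgr5 and Axin2 are also among the markers that named these cells. The destruction-complex list had a median of −0.040, with no member beyond 1.5-fold, and intestinal stem cell genes −0.12 (Prom1 −0.58, Rgmb 0.71).

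Type I interferon genes had a median of −0.52 (Ifit1 195 and 96.8 CPM, −1.01; Ifit2 −0.93; Rsad2 −0.83; Usp18 −1.56), while interferon-gamma genes were at 0.12 (Gbp2 1.00, Igtp 0.63, Iigp1 0.391 and 8.52 CPM) and MHC class I at 0.31 (B2m 84.7 and 143 CPM, 0.76; H2-Q7 1.03). In stem- or progenitor-like cells together the type I interferon median was −0.15. It was lower in the subclusters of these cells led by Unc5d (−0.32), Clstn2 (−0.65), Fut9 (−0.73) and Ube2c (−0.67). Antimicrobial genes went both ways: Lcn2 (348 and 135 CPM, −1.36) and S100a8 (−0.58) were lower and Slpi (165 and 744 CPM, 2.17) higher. S100a8 is also on the neutrophil marker list, whose sum stood at −0.52 in the empty droplets, so its ratio is not shown to be epithelial. Tuft genes had a median of −0.53 (Avil 57.1 and 28.2 CPM, −1.02; Sh2d6 −1.81). Regenerative genes were at −0.13 (Il33 −0.88), YAP targets at −0.19 (F3 0.96, Amotl1 −0.87), proliferation at −0.083, glycogen metabolism at −0.14, cholesterol synthesis at −0.067, glycolysis at 0.0084, oxidative phosphorylation at 0.072, NF-kB response at −0.054 and Paneth-like genes at 0.31 (Defa17 0.64), which turned to −0.37 in stem- or progenitor-like cells, −0.16 with every barcode of 500 UMIs and −0.085 without doublet removal. The dissociation stress list had a median of −0.023. Its heat-shock genes Hspb1 (718 and 204 CPM, −1.81), Hspa1b (−1.55) and Hspa1a (−1.31) were lower in the KO library, however. Collagen and other matrix genes of the fibroblast list were higher in the epithelial class (median 1.57; Col3a1 1.52 and 9.34 CPM) at low levels, beside fibroblast shares of 0.273% and 1.98% of cells.

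**Figure D3:**
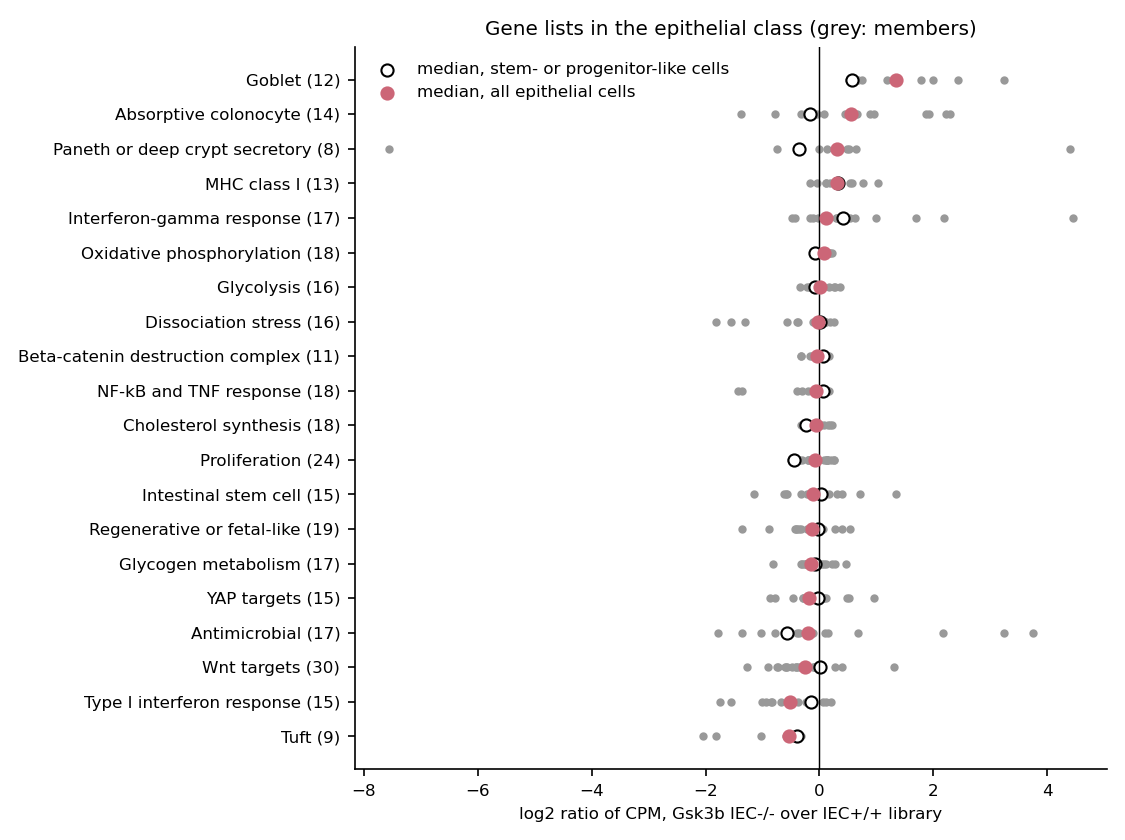
Log2 ratio of CPM (horizontal axis), IEC−/− over IEC+/+ library, per gene list in the epithelial class, with the number of measured members in brackets; grey points are members, red points the median over all epithelial cells and open circles the median in stem- or progenitor-like cells. The goblet median was 1.34 and 0.57, the Wnt median −0.26 and 0.010, and the type I interferon median −0.52 and −0.15. The latter was −0.32, −0.65, −0.73 and −0.67 in the stem- or progenitor-like subclusters led by Unc5d, Clstn2, Fut9 and Ube2c.

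T cells of the KO library carried more RNA of the naive list and less of the type 17 and Treg lists. Treg-like cells were 39.8% of WT and 27.4% of KO T cells, CD8 cytotoxic cells 10.7% and 20.7%, type 17 or gamma-delta cells 16.5% and 11.9%, naive cells 6.96% and 18.7%, and NK cells or innate lymphoid cells 5.09% and 6.06%. A subcluster led by Il17a, Ermn and Furin, with 123 WT and 54 KO cells, was given no name and is in none of these shares. At subclustering resolution 1 Treg-like cells were 19.3% and 16.9%, with a cluster that scored highest for Treg markers (174 WT and 106 KO cells) unnamed, and 40.9% and 30.8% with it. At 0.3 the only cluster named CD8 cytotoxic, 4.72% and 10.9% of T cells, was led by the mitotic genes Pclaf and Birc5. A cluster led by Gramd3, Gm2682 and Ccl5 (136 WT and 261 KO cells) scored highest for CD8 cytotoxic markers and went unnamed. No cluster was named naive at 0.3. The genes furthest above WT were Il12rb2 (32.6 and 135 CPM, 2.05), Iigp1 (1.84), Ly6c2 (1.65) and Tbx21 (25.4 and 71.6 CPM, interval 1.13 to 1.88), and furthest below were Il17f (103 and 5 UMIs, −4.30), Ccr9 (58.3 and 7.26 CPM, −3.01), Ermn (−2.14) and Il17a (1351 and 389 CPM, −1.79). The type 17 list had a median of −1.04 (Il23r −1.07, Trdc −1.01, Tcrg-C1 −0.72) and the Treg list −0.66 (Foxp3 −0.66, Il2ra −0.71, Ctla4 −0.80, Gzmb −1.35), while the naive list was at 0.54 (Tcf7 0.60). Cytotoxic genes were at 0.45 (Nkg7 0.82, Ccl4 0.66), exhaustion genes at −0.27 (Havcr2 −1.28, Cd160 1.33) and proliferation genes at 0.55, with 24 of 24 members above 0 (Mki67 0.64). In T cells type I interferon genes had a median of 0.25 and interferon-gamma genes of 0.31. Most WT T cells lay in clusters led by Tnfrsf4, Penk and Ikzf2 (352 WT and 229 KO cells) and by Il17a, Trdc and Cxcr6 (245 and 129), and most KO T cells in the former and in 1 led by Ccl5, Ms4a4b and Nkg7 (186 and 371).

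Macrophages of the KO library had lower MHC class II and Hspa1b RNA and higher Ccl5. The genes furthest above WT were Ly6i (6.59 and 33.8 CPM, 2.36), Tnfsf9 (1.41), Ccl5 (329 and 722 CPM, 1.13) and Chil3 (137 and 287 CPM, 1.06), and furthest below were Hspa1b (576 and 133 CPM, −2.11), H2-M2 (62.1 and 13.7 CPM, −2.18), Ifit2 (81.2 and 20.5 CPM, −1.99) and AW011738 (−2.03). MHC class II genes had a median of −0.56 with 7 of 7 members lower, type I interferon genes −0.28, dissociation stress genes −0.28 and interferon-gamma genes 0.13. Hspa1b is on the dissociation stress list and stood at 469 CPM in the WT and 186 CPM in the KO empty droplets. Sample handling was not tested, and with 1 library per genotype it cannot be told apart from genotype here. In both libraries the cluster led by F13a1, Saa3 and Chil3 held the most of these cells (534 WT and 286 KO), followed in WT by the one led by Apoe, C1qc and C1qa (359 and 185) and in KO by the one led by Ccl24, Arg1 and Dcstamp (285 and 246).

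Neutrophils of the KO library had far lower Camp and Ngp, lower glycolytic RNA and higher interferon-gamma response RNA. Camp (405 and 5.64 CPM, −6.17), Ngp (1082 and 41.4 CPM, −4.71), Chil3 (73.2 and 7.33 CPM, −3.32) and Prok2 (184 and 22.5 CPM, −3.03) stood furthest below WT, and Dusp2 (44.6 and 197 CPM, 2.14), Slc38a1 (78.1 and 275 CPM, 1.82), Elmod3 (1.79) and Adgrv1 (1.93) furthest above. Median-of-ratios scaling moved all neutrophil ratios by 0.13 and turned none of the directions given here. Interferon-gamma genes had a median of 0.88 with 14 of 14 members higher (Cxcl10 0.97, Gbp2 30.3 and 90.5 CPM, 1.58) and MHC class I genes 0.52 (Nlrc5 1.40, Tap1 0.91). Type I interferon genes were also higher in neutrophils, with a median of 0.47 and 10 of 14 members above 0. Glycolysis genes were at −0.59 (Gapdh 2617 and 1663 CPM, −0.65; Aldoa −0.77; Ldha −0.72), hypoxia genes at −0.37 (Ero1l −1.49) and activation genes at 0.17 (Nlrp3 0.84 and Il1rn 0.64 higher, S100a8 −0.82 lower). WT neutrophils lay in a cluster led by Ccrl2, Acod1 and Hcar2 (1637 cells) and in 1 led by Ngp, Ifitm6 and Mmp8 (1091 cells), whereas the KO library had 3517 and 182 cells in them.

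**Figure D4:**
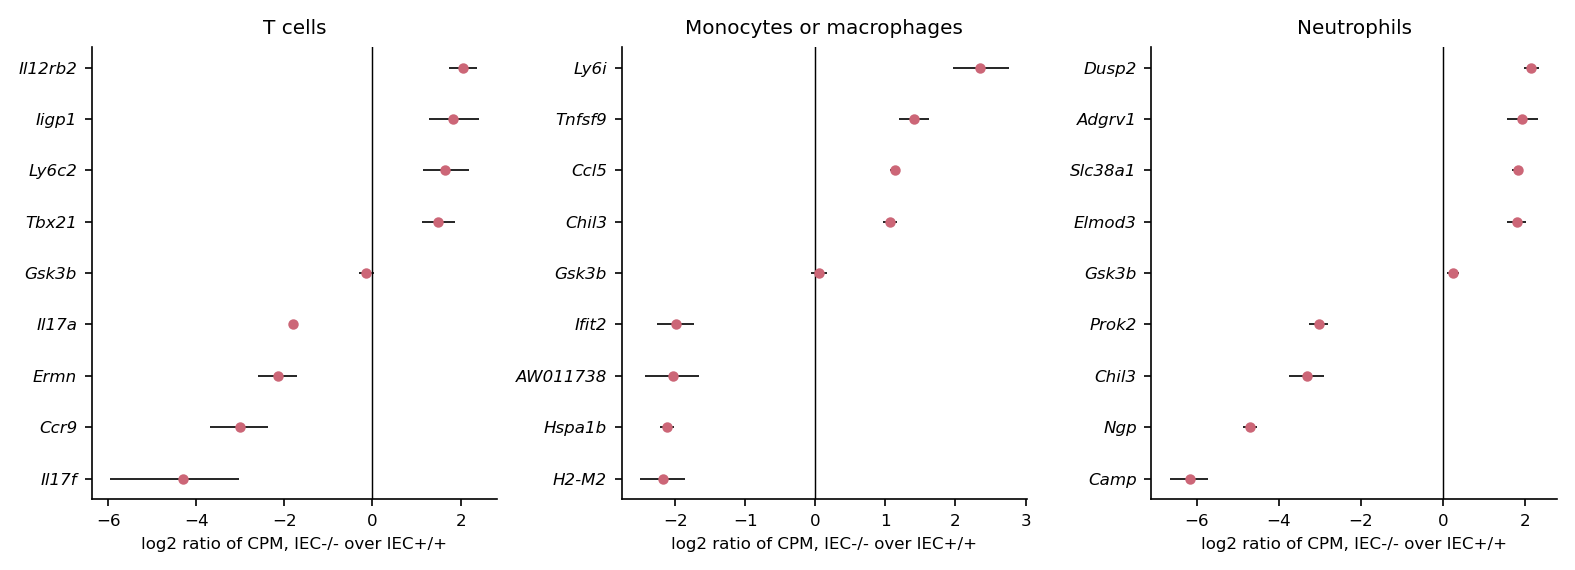
Log2 ratio of CPM (horizontal axes), IEC−/− over IEC+/+ library, of Gsk3b and the genes named by rule in T cells, monocytes or macrophages, and neutrophils; bars are exact 95% counting intervals. Il17f stands at −4.30 in T cells, Hspa1b at −2.11 in macrophages and Camp at −6.17 in neutrophils.

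In B cells (119 WT and 504 KO) Nr1h2 (2.43, interval 0.82 to 4.75), Pik3r1 (1.64, 0.76 to 2.68), Atl2 (1.83, 0.73 to 3.18) and Hspa1a (585 and 1014 CPM, 0.79) were higher in the KO library. Nr1h2, Pik3r1 and Atl2 rest on 3, 11 and 7 WT UMIs. In KO B cells Nr1h2 (42.8 CPM) and Atl2 (65.9 CPM) stood near the KO empty droplets (40.0 and 64.7 CPM). MHC class II genes differed little (median 0.032). The genes furthest below WT were Siglech (55 and 0 UMIs, upper bound of the log2 ratio −5.86), Ccr9 (−6.38), Srgap3 (−6.16) and Tex2 (−4.47). With every barcode of 1000 UMIs the WT UMIs fell to 15 for Siglech and 3 for Srgap3. Leaving out cells with a Siglech UMI took the WT UMIs of Ccr9 from 83 to 0, of Srgap3 from 71 to 1 and of Tex2 from 66 to 5, with 4, 4 and 12 KO UMIs before and after. Siglech is on the fixed dendritic cell list. These ratios therefore describe Siglech-holding cells within the WT class and not the rest of its B cells.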

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

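The empty droplets were read as a record of RNA from broken cells, and these signals were picked by a rule for data outside the main comparisons: a class's marker sum above the WT library by over 1.5-fold, a size chosen for this test after the result was seen. B cell markers made up 38.8 CPM of the empty droplets in the WT and 114 CPM in the KO library (log2 1.56, interval 1.38 to 1.74), with 11 of 11 markers higher in KO. Fibroblast markers made up 233 and 528 CPM (log2 1.18, interval 1.11 to 1.26), with 15 of 15 markers higher. Both stand beside larger shares of the same classes among KO cells (log2 1.99 for B cells and 2.86 for fibroblasts), measured in other barcodes of the same libraries. Neutrophil markers (log2 −0.52) and plasma cell markers (−0.42), by contrast, were lower in the empty droplets of the KO library, while the same classes held larger shares of its cells (0.35 and 0.60, although plasma cells were 42 WT and 44 KO cells with every barcode of 500 UMIs). Epithelial cells (markers 0.16, share −0.13) and endothelial cells (markers −0.066, share 0.68) also differed in direction. Mast cell markers (log2 −2.22) and macrophage markers (−0.77) were lower in the empty droplets of the KO library, as were the shares of these classes among its cells (−1.33 and −0.83), and erythroid genes were lower too (−2.26). No explanation was weighed for these values, and no technical or biological cause was tested.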

How the results depend on the processing

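The settings of the other classes, those in stem- or progenitor-like cells, without shallow clusters or subclusters of 1 library, with subclusters weighted alike, without Siglech cells, and with the free-RNA share from haemoglobin were tests chosen after the data were examined. Of 833 alternative values of 61 gene ratios, without 8 that had under 20 UMIs, 825 kept their sign, as did 483 of 513 for 36 list medians and 96 of 101 for 22 shares. Among results beyond 1.5-fold, 767 of 768, 64 of 64 and 62 of 63 did. The 8 left out were B cell values of Siglech, Ccr9, Srgap3 and Tex2 with 0 to 15 WT UMIs. The gene tally thus leaves out settings in which these genes lost most of their WT UMIs. With every barcode of 500 UMIs the log2 share ratios were 0.038 for epithelial cells, 2.10 for fibroblasts and −0.20 for endothelial cells, and the epithelial medians 1.17 for goblet and −0.16 for Paneth-like genes. The epithelial share was 0.0067 at Leiden resolution 0.5 and 0.024 with each library clustered alone. With unnamed clusters counted in the class they scored highest for, a step also chosen after the data were examined, it was −0.062 with every barcode of 500 UMIs, −0.13 at resolution 0.5 and −0.12 with each library alone, so these 3 reversals came from clusters left unnamed. Without doublet removal fibroblasts were at 2.27, Gsk3b at −0.17, Wnt targets at −0.37 and Paneth-like genes at −0.085. The goblet-like share was 2.29 at subclustering resolution 0.3 and 1.43 at 1. It was 0.83 at 0.3 with an unnamed cluster counted that was led by Lyz1, Ang4 and Clps. The stem- or progenitor-like share was 0.044 at 0.3 (−0.15 with unnamed clusters counted) and 0.17 at 1. The Treg-like share was −0.19 at 1 (−0.41 with unnamed clusters counted), and unnamed T cells were 0.35 at 0.3. A 10% mitochondrial limit put goblet genes at 1.28. Median-of-ratios scaling gave Gsk3b −0.079, goblet 1.40, destruction complex 0.015, NF-kB 0.0014 and stress genes 0.032. A mean over cells gave Gsk3b −0.085, goblet 0.97, proliferation 0.036, NF-kB 0.015, stress 0.017 and type 17 genes in T cells −0.90. With free RNA subtracted Gsk3b was −0.079 and the destruction complex 0.014; with the share from haemoglobin Gsk3b was −0.31, Wnt −0.43, goblet 1.38, NF-kB 0.17, type 17 −1.40, neutrophil interferon-gamma 1.47 and activation genes −0.013, and macrophage interferon-gamma genes −0.0099. Cells thinned to the same depth gave Gsk3b −0.10, Wnt −0.15, goblet 1.17, type 17 −0.87 and neutrophil interferon-gamma genes 0.71, which were 0.72 with members of 50 UMIs. Without subclusters of 1 library Gsk3b was −0.094, Wnt −0.18 and goblet 1.18. In stem- or progenitor-like cells only, Gsk3b was 0.0096, Adh1 −0.17, Wnt 0.010, destruction complex 0.054, stem cell genes 0.024, absorptive −0.17, goblet 0.57, Paneth-like −0.37, oxidative phosphorylation −0.074, NF-kB 0.063 and stress genes 0.0067. Subclusters weighted alike gave Gsk3b −0.053, Wnt −0.026 and goblet 0.19. Fewer cell types enter the settings of the last 3 kinds by construction; for the others, beyond those from unnamed clusters, the cause was not tested. No paired analysis was possible because each genotype has 1 library. Depth limits B cells most, with 377635 WT UMIs in the class.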

Other observations

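The tests of goblet RNA over the whole epithelium and within goblet-like cells, of free RNA and of an effect limited to the deleted cells behind Slc15a2, and of depth, free RNA and blood behind the neutrophil genes were chosen after the result was seen; the others were written before their values were known.

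Goblet genes were higher in the KO epithelium (median log2 1.34), and the median of the same list was above 0 in every other class compared. Free RNA alone does not account for the epithelial level, since the median goblet gene had 7.79 times the CPM in KO epithelial cells that it had in KO T cells. The epithelial class includes the goblet-like cells, so this value cannot tell how much free RNA adds to the KO over WT ratio. In KO stem- or progenitor-like cells, however, the median gene had 0.824 times its T cell level, so the ratio of 0.57 there may come from free RNA. With the T cell level taken off, only 3 of 12 genes stayed above 0 in both libraries in these cells, so their median of −0.26 decides nothing, and it stays open whether a larger share of goblet-like cells alone gives the epithelial difference. Within goblet-like cells the list median was −0.47 together, with a highest upper bound of 0.19 over their 3 subclusters. It was 0.15 (0.085 to 0.19) in the one led by Zg16, −0.13 in the one led by Fcgbp and −0.98 in the mitotic one, with 12 WT cells. The same 12 genes named these cells, so the medians cannot decide whether a higher level per goblet-like cell gives the epithelial difference. A difference linked to the deletion and one between animals were not tested, with 1 library per genotype.

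Slc15a2, singled out after its values were seen, was lower in the KO library in each of the 5 classes compared: 11.9 and 1.37 CPM in epithelial cells (log2 −3.13), 41.4 and 8.84 CPM in T cells (−2.23), −3.07 in B cells, −2.53 in monocytes or macrophages and −2.17 in neutrophils; plasma cells, with 7 and 12 UMIs, showed no such difference. It lies on chromosome 16 from 36750177 to 36784962 (mm10), 1304 kb from Gsk3b. The highest upper bound among the 4 other classes compared was −1.63, so the difference was not limited to the epithelial class. Because the gene was singled out after these ratios were seen, the bound is no separate test of an effect limited to deleted cells. Free RNA as the whole of the ratio is argued against. All of the empty-droplet CPM (12.5) was taken off the lower bound of the WT level. The upper bound of the KO level then still stood at a log2 of −0.70 or less in these 4 classes. In epithelial cells that bound was −1.85 with 0.431 of the empty-droplet CPM taken off, the highest share that markers of 6 other classes allowed. A strain difference carried along with the targeted gene may explain such a ratio, but of the 22 genes within 2 Mb of Gsk3b measured in 4 or more classes, 0 others differed by the same rule, against 46 of 10293 genes overall. The sources used here name no strain, and this count cannot exclude a variant that acts on 1 gene, so a strain difference and an effect of the deletion that reaches other cells cannot be told apart.

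Camp, Ngp, Chil3 and Prok2 were lower in KO neutrophils. With cells thinned to the same depth their median log2 ratio was −4.02. Thinning leaves a gene's expected share of a cell's UMIs unchanged, and CPM already divides by the class total. This value therefore cannot decide whether depth acted through the calling or clustering of cells. Free RNA is argued against, since each gene had at least 5.8 times the CPM in WT neutrophils that it had in the empty droplets. More blood in the WT sample may bring such cells: erythroid RNA in the empty droplets was lower in the KO library (log2 −2.26), but B cells, which blood also brings, were higher there (1.20% and 4.78% of cells). Blood and a difference in neutrophil maturation linked to the genotype cannot be told apart here, because each genotype has 1 library and blood was not measured on its own.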
